A study of Danio rerio with 36 samples.

How the data were processed

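Gene expression was measured in whole zebrafish (Danio rerio) embryos of a transgenic line, Tg(fli1a:EGFP)y1, in which blood vessel cells carry a green fluorescent protein. From about 3 hours post fertilization (hpf) the embryos were held in sealed glass vials in medium with methyl tert-butyl ether (MTBE, a fuel additive) at 5, 0.625 or 0.00625 mM, or in medium alone as the control. They were collected at 3 stages named 6-somites (about 15 hpf), 21-somites (about 24 hpf) and Prim-5 (about 30 hpf). Each sample was a pool of 15 embryos. The 12 groups of stage and dose had 3 samples each, which gave 36 one-colour Affymetrix arrays. Per the labels, total RNA was extracted, amplified with a NuGEN kit and labelled with biotin.

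The authors deposited 1 table of processed values in log2 units, with 15617 probe sets on each of the 36 arrays. The unit was read from the values, which ran from 0.599 to 13.24 and so fit no linear scale. The tools for background correction, summary and normalization are not given in the sources used here. Array medians lay between 3.41 and 3.62, and no array was a copy of another. Scanner files were not used here, so signal over background and scan batches were not examined. Arrays have no read depth, and the 3 arrays of each group limit the precision of every value. The 115 control probe sets of the manufacturer were left out, and 15502 probe sets were tested. Of these, 10795 had 1 gene symbol, 135 had several and 4572 had none. The symbols covered 8796 genes. No genome positions came with the table.

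The groups, comparisons, tests, gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. In R 4.3.3, limma 3.58.1 (two-sided) fitted 1 linear model with the 12 groups to all arrays, followed by its eBayes step, and a probe set counted as changed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons were each MTBE dose against the controls of the same stage, the mean of these differences over the 3 stages, a linear trend over the 4 doses in order within each stage, a moderated F test of whether the effect of 5 mM differed between stages, and each stage against the one before it in controls. All comparisons of doses within a stage share the same 3 control arrays. The median standard error of a difference between 2 groups was 0.141 on the log2 scale. The p-values measure only the spread between these pooled samples.

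Named genes were chosen by rule among probe sets with 1 symbol. For each comparison these were the changed genes with the largest rise and fall whose arrays did not overlap between the groups. Up to 10 each way were taken for 5 mM, 3 for lower doses and 5 for controls and trends. Where none passed, the 3 genes with the smallest p were taken, and they are said not to pass. The vascular growth factor genes vegfaa, vegfab and vegfc were named in every comparison of 5 mM, but vegfab had no probe set with its symbol. For each gene list described, the 4 members with the smallest p were named. Genes of other lists that passed over their list alone were also named, and that addition was made after their values were seen.

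The 24 gene lists were written from textbook knowledge. They covered blood vessel, hypoxia response, glycolysis, red blood cell, white blood cell, heart muscle, skeletal muscle, nervous system, eye and lens, pigment cell and neural crest, notochord and cartilage matrix, epidermis, hatching gland, yolk and lipid transport, segmentation and tailbud, cell cycle, p53 and apoptosis, xenobiotic metabolism, oxidative stress response, heat shock and chaperone, endoplasmic reticulum stress and amino acid response, immediate early and stress signalling, cholesterol synthesis, and circadian clock. The hatching gland list had 4 genes on the array, under the minimum of 5, and was not tested. The other 23 lists were tested with camera of limma, two-sided, with a preset correlation between genes of 0.01 and the probe set with the highest mean for each gene, and adjusted over the 23 lists. The test was repeated with a correlation estimated for each list. Counts of changed members are given both over all genes and adjusted over the list alone. Tests of lists between control stages, tests of lists between stages at 5 mM, and all values without the 2 control arrays low in yolk transcripts were added after the data were seen.

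A stage score placed each array along development. It was the mean log2 value of the 300 probe sets that rose most minus that of the 300 that fell most between controls of the 2 other stages, and 5 mM and control arrays were compared by exact two-sided permutation tests. The order of doses was read as the percent of probe sets changed at 5 mM that moved the same way from 0.00625 to 0.625 mM.

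The tests were tested on simulated data with the spread of the real arrays and 3 arrays a group. Each comparison was simulated in 1 run, with 50 probe sets changed at each size of 0.5, 0.75, 1 and 1.5, and independent noise. A log2 change of 0.5 was called in 54% of 50 changed probe sets in a single stage, 0.75 in 80% and 1 in 100%, with 4 false calls. So many true changes loosen the adjusted threshold. Where only 0 or 1 probe sets pass, a change of the same size would be called less often, so these shares do not carry over. For the mean over stages, 0.5 was called in 90%, with 12 false calls. For the F test 0.5 was called in 20% and 1.5 in 96%, with 7 false calls. For the dose trend 0.5 was called in 42% and 1 in 100%, with 19 false calls. For the mean and the trend the false calls were a larger share of all calls than the threshold allows. All 5 lists shifted by 0.2 were called and 0 of the others. For groups without a change, residuals of whole arrays were drawn with replacement and added to the control means, which keeps correlations between genes. Camera with the preset correlation called at least 1 list in 42 of 100 draws and at most 4 lists, and camera with an estimated correlation in 1 of 100. Other splits of the 6 real arrays with 5 mM and control at 21-somites, which mix the 2 groups, called 2 to 4 lists each. A shift of 10% along the stage score was read as 9.19%.

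The other settings were quantile and cyclic loess normalization, a constant of 50 added on the linear scale, only probe sets at or above the median level, only the arrays of the stage, eBayes with trend and robust settings, a replicate block, and leaving out each replicate. For lists they were the mean of the probe sets of a gene and the estimated correlation, and for the stage score 100 or 1000 probe sets a side. Array weights, the fits without the 2 control arrays low in yolk transcripts, and the dose order of the 100 probe sets with the smallest p were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.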

Results

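The data were 36 arrays of whole zebrafish embryos, 3 arrays for each of 4 doses of MTBE at each of 3 stages. Replicates of a group correlated between 0.984 and 0.9958 over all probe sets. The first principal component held 65.9% of the variance and ordered the arrays by stage. The third held 3.5% and set control replicate 1 at 6-somites and control replicate 1 at 21-somites apart from all other arrays. In these 2 controls, the list of yolk and lipid transport genes had a mean log2 level of 4.73 against 5.48 and 5.59 in the other controls at 6-somites, and of 4.78 against 6.17 and 6.14 at 21-somites. The apolipoprotein gene apoa2, named after this component was seen, lay at a log2 difference of -2.44 and -3.84 from the mean of the other 2 controls, and at -0.01 for control replicate 1 at Prim-5. These 2 arrays are called the yolk-poor controls. Comparisons with the controls of these stages used them unless said otherwise. Control probe sets for 2 red fluorescent proteins, which the line is not described as carrying, had mean log2 levels of 2.18 and 2.98. Probe sets whose mean lay under the lower of these were not shown to lie above background. This held for the means over all arrays of vegfaa, or30bx1, cpb1, lipca, mrc1a, neurod1, plvapb, snap25b, th, txnipb, epoa, ldha, casp8, fam210ab, tnr and rem1 (which was brighter at 6-somites) and for bmp5 at 6-somites, and their log2 differences are not exact. Levels between the 2 red fluorescent probe sets were not shown to lie above background either. Among these were lpcat4 at a mean of 2.7, lhx2a in every group and mylpfa in 6-somites controls at 2.48.

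**Figure D1:**
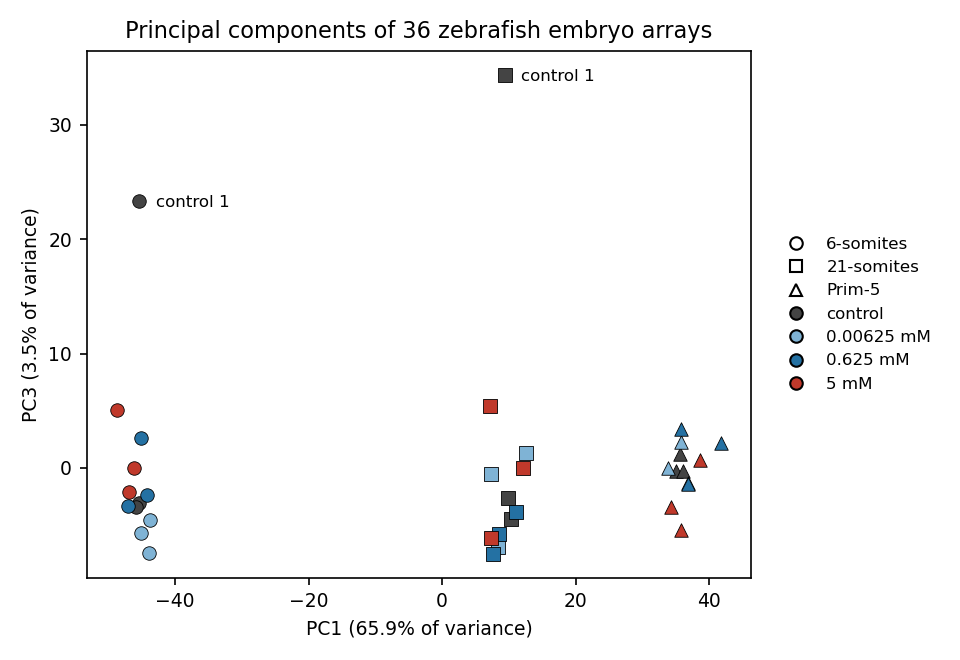
Each point is 1 array, placed by principal component 1 (65.9% of the variance) and component 3 (3.5%), with shape for stage and colour for MTBE dose. The yolk-poor controls at 6-somites and 21-somites lie apart on component 3.

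**Figure D2:**
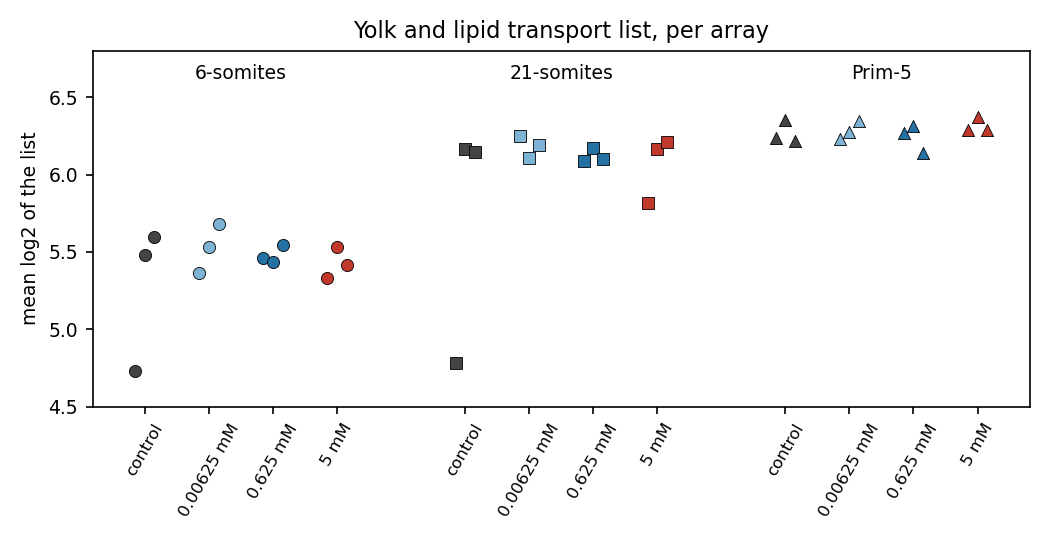
Each point is 1 array, and the vertical axis is its mean log2 level over the 32 yolk and lipid transport genes on the array, by stage and MTBE dose. Control replicate 1 lies at 4.73 at 6-somites and at 4.78 at 21-somites.

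Control embryos showed which programs ran between stages and whether the stage labels hold. From 6-somites to 21-somites, genes of the contractile apparatus rose most. The fast myosin genes myhz1.3 and myl1 rose by a log2 change of 6.53 ± 0.17 and 6.48 ± 0.15 (SE, n = 3 arrays a group), the calcium pump gene atp2a1 by 6.07 ± 0.15 and the myosin light chain gene mylpfa by 4.61 ± 0.16. The embryonic globin gene hbbe3 rose by 4.96 ± 0.17. The transcription factor gene six7 changed by -3.89 ± 0.15, szl, which acts in dorsoventral patterning, by -3.47 ± 0.17, si:ch211-152c2.3 by -3.23 ± 0.14, the leukocyte gene lcp1 by -2.77 ± 0.17 and the ventral homeobox gene vox by -2.40 ± 0.16. With limma, 3505 of 15502 probe sets changed, 1813 higher and 1692 lower at 21-somites, of which 467 rose and 176 fell more than 2-fold. The balance depended on scaling, with 1699 higher and 2013 lower after quantile normalization and 1938 and 1595 after cyclic loess.

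Of the 23 lists, 9 changed between these stages, 7 higher and 2 lower. In the skeletal muscle list 28 of 34 genes rose and 1 fell over all genes, and 29 rose and 1 fell adjusted over the list alone, with actc1b at 3.42 beside myl1, atp2a1 and mylpfa (camera adjusted p = 5.62e-38). The nervous system list rose with 21 of 42 genes over all genes and 23 adjusted over the list alone, among them the neuronal sodium pump gene atp1a3a at 2.68 ± 0.15, the radial glia gene fabp7a at 2.53 ± 0.17, dpysl3 at 1.76 and cplx2a at 2.13 (adjusted p = 3.99e-10). The red blood cell list rose with 12 of 21 genes higher and 3 lower by both counts, among them hbae3 at 4.27 ± 0.18 and the heme synthesis gene cpox at 2.1 ± 0.15 and urod at 1.53 (adjusted p = 6.02e-07). The glycolysis list rose with 9 of 22 genes over all genes and 10 adjusted over the list alone, led by the aldolase genes aldoab at 3.39 ± 0.15 and aldocb at 2.1, eno1a at 2.30 and gapdhs at 1.18 (adjusted p = 0.000172). The notochord and cartilage matrix list rose with 10 of 19 genes higher and 4 lower, or 12 and 4 adjusted over the list alone, led by the collagen genes col9a2 at 3.16 ± 0.18, col2a1a at 2.33 ± 0.12 and col11a1a at 2.29 and by hapln1a at 2.44 (adjusted p = 5.79e-05). The segmentation and tailbud list fell with 22 of 27 genes by both counts, among them cdx4 at -1.47 ± 0.11, tbx6 at -1.25 ± 0.14, sp5l at -1.53 and mespba at -1.43, and 1 gene rose adjusted over the list alone (adjusted p = 4e-15). These 6 lists also passed with an estimated correlation, with the highest adjusted p = 0.0307 for notochord and cartilage matrix.

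The other 3 lists passed only with the preset correlation. The heart muscle list had 8 genes higher and 6 lower of 18 by both counts, among them the ventricular myosin gene myh7 at 4.25 ± 0.16, cmlc1 at 3.71, ttn.2 at 2.33 and tnnt2a at 2.87 (adjusted p = 0.0105 and adjusted p = 0.086 with an estimated correlation). The cell cycle list had 16 of 57 genes lower and 1 higher, or 19 and 1 adjusted over the list alone, led by the replication licensing gene cdt1 at -0.95 ± 0.15, with gmnn at -0.61, ccnb2 at -0.65 and chek1 at -0.69 (adjusted p = 0.00177 and adjusted p = 0.0795 with an estimated correlation). The blood vessel list had 6 of 27 genes higher and 4 lower, or 10 and 4 adjusted over the list alone (adjusted p = 0.0471 and adjusted p = 0.086 with an estimated correlation). Its members crip2, s1pr1 and plxnd1 rose by 2.22 ± 0.14, 1.34 ± 0.17 and 0.82 ± 0.14, and gata2a changed by -1.87 ± 0.14. The yolk and lipid transport list gave camera adjusted p = 0.0944 with all arrays and adjusted p = 0.000166 without the yolk-poor controls, both with the preset correlation. With an estimated correlation it did not pass with all arrays, and that setting was not run without the yolk-poor controls.

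**Figure D3:**
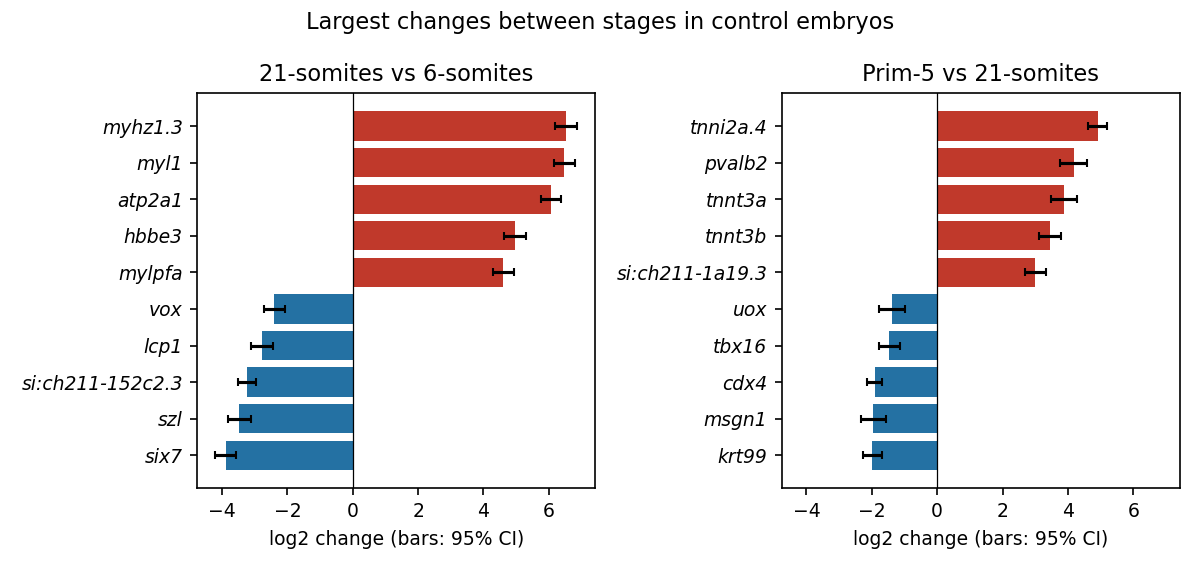
Bars are log2 changes between consecutive stages in control embryos (n = 3 arrays a group) for the 5 genes with the largest rise and the 5 with the largest fall, with 95% confidence intervals. The largest rise was 6.53 for myhz1.3 at 21-somites and 4.91 for tnni2a.4 at Prim-5.

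From 21-somites to Prim-5 the fast muscle program went on and tailbud genes fell. The troponin genes tnni2a.4, tnnt3a and tnnt3b rose by 4.91 ± 0.14, 3.87 ± 0.20 and 3.46 ± 0.17, the calcium buffer gene pvalb2 by 4.18 ± 0.20 and si:ch211-1a19.3 by 3.00 ± 0.16 (SE, n = 3). The keratin gene krt99 changed by -1.98 ± 0.14, and the tailbud genes msgn1, cdx4 and tbx16 by -1.95 ± 0.18, -1.91 ± 0.11 and -1.46 ± 0.15, and the urate oxidase gene uox by -1.38 ± 0.20. With limma 1091 probe sets changed, 672 higher and 419 lower, of which 184 rose and 18 fell more than 2-fold. The counts higher and lower were 691 and 437 with quantile normalization, 823 and 275 with cyclic loess, and 382 and 400 with only probe sets at or above the median level.

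Between these stages 8 lists changed, 7 higher and 1 lower. The skeletal muscle list had 21 of 34 genes higher and 3 lower over all genes, or 23 and 3 adjusted over the list alone (camera adjusted p = 2.48e-36). Glycolysis rose with 13 of 22 genes, or 14 higher and 1 lower adjusted over the list alone, led by aldoab at 1.47 ± 0.15, gapdhs at 1.64 ± 0.16, pgam2 at 1.42 and eno3 at 1.38 (adjusted p = 8.9e-12). The nervous system list rose with 18 of 42 genes, or 18 and 1 lower adjusted over the list alone, among them islr2 at 1.47 ± 0.17, fabp7a at 1.38 ± 0.17, the axon growth gene gap43 at 1.13 ± 0.14 and gad1b at 1.14 (adjusted p = 3.32e-10). The segmentation and tailbud list fell with 10 of 27 genes, or 12 adjusted over the list alone, with tbx6 at -1.07 beside cdx4, msgn1 and tbx16 (adjusted p = 1.31e-09). Red blood cell genes rose with 7 higher and 1 lower of 21, or 8 and 2 adjusted over the list alone, led by the anion exchanger gene slc4a1a at 1.79 ± 0.17, with hbae3 at 1.54, hbbe3 at 1.17 and klf17 at -0.67 (adjusted p = 6.48e-05 and adjusted p = 0.0442 with an estimated correlation).

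The remaining 3 lists did not pass with an estimated correlation. The oxidative stress response list had 5 of 30 genes higher and 1 lower, or 7 and 1 adjusted over the list alone, with the biliverdin reductase gene blvrb at 1.52 ± 0.20, gstp1.2 at 0.92, prdx1 at 0.73 and nqo1 at -0.51 (adjusted p = 0.0003 and adjusted p = 0.134 with an estimated correlation). The heart muscle list had 6 of 18 genes higher and 1 lower, or 7 and 2 adjusted over the list alone, with cmlc1 at 1.33, myl7 at 1.45 ± 0.20, ttn.2 at 0.89 and myh7 at 0.86 (adjusted p = 0.0208, adjusted p = 0.158 with an estimated correlation and adjusted p = 0.0772 without the yolk-poor controls). The yolk and lipid transport list had 7 of 32 genes higher, or 13 adjusted over the list alone, with the retinol carrier gene rbp4 at 1.87 ± 0.31, cp at 1.09, apoea at 1.34 and apoc2 at 1.07 (adjusted p = 5.24e-07 and adjusted p = 0.381 with an estimated correlation). It compared against a stage with a yolk-poor control, and without the yolk-poor controls it gave adjusted p = 0.306.

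The study asked what MTBE did at stages when the cardiovascular system forms. Per the labels, 5 mM causes vascular lesions and lowers vegfa, and 0.625 mM is the highest dose without an observed adverse effect. The vascular growth factor gene vegfaa was read by 1 probe set close to the low end of the array (mean log2 level 1.69). Its log2 difference between 5 mM and control was -0.20 ± 0.12 at 6-somites, 0.16 ± 0.12 at 21-somites and -0.00 ± 0.12 at Prim-5 (SE, n = 3), with limma adjusted p = 0.675, 0.771 and 1. The 95% confidence intervals ran from -0.45 to 0.05, from -0.09 to 0.41 and from -0.25 to 0.25. Since the probe set was not shown to lie above background, these intervals do not bound the change of the transcript. For vegfc the differences were 0.10, -0.03 and -0.06, each ± 0.19. Neither gene passed the test at any stage.

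The blood vessel list did not change with 5 mM at any stage. Its median log2 difference was 0.07 at 6-somites (camera adjusted p = 0.814), -0.10 at 21-somites (0.181) and -0.00 at Prim-5 (0.822), where the mean was 0.01 and the test pointed up. At each stage 0 of its 27 genes passed, over all genes or adjusted over the list alone. The members with the smallest p at 6-somites were the receptor genes ephb4a at 0.25 ± 0.14 and flt4 at 0.26 ± 0.17 and the ligand gene angpt1 at 0.27 ± 0.16. At 21-somites they were the junction gene cldn5a at 0.41 ± 0.14, hey2 at -0.35 ± 0.14, flt4 at -0.34 ± 0.17 and mrc1a at -0.28 ± 0.14. At Prim-5 plvapb lay at 0.46 ± 0.16, gata2a at -0.26 ± 0.14, mrc1a at 0.22 ± 0.14 and cxcr4a at 0.17 ± 0.13. The hypoxia response list had medians of 0.05, -0.08 and -0.00 (adjusted p = 0.814, 0.461 and 0.897), and 0 of its 23 genes passed. Its leading members were arnt2 at 0.32 ± 0.13 and igfbp1a at 0.36 ± 0.20 at 6-somites, with mxi1 at 0.18. They were arnt2 at -0.41 ± 0.13, egln3 at -0.83 ± 0.44, epoa at -0.27 and bnip3lb at 0.35 at 21-somites, where bnip3lb lay at -0.04 without the yolk-poor controls. At Prim-5 they were epas1a at -0.30 ± 0.14, p4ha1b at 0.41 ± 0.21, higd1a at -0.31 and mxi1 at 0.25.

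At 6-somites no gene passed with 5 mM. The signalling ligand gene bmp5 lay 0.70 ± 0.13 higher on the log2 scale (adjusted p = 0.112), the odorant receptor gene or30bx1 0.83 ± 0.17 (0.158) and the carboxypeptidase gene cpb1 0.52 ± 0.12 (0.22), and these are the 3 with the smallest p. With limma 0 probe sets changed, and 1334 had an unadjusted p under 0.05 where 775.1 were due by chance on average. The spread of that number is not known, and at Prim-5 with 0.00625 mM the count was 313. An excess over 775.1 was therefore not read as true changes. Leaving out control replicate 3 at 6-somites brought bmp5 past the threshold (0.83, adjusted p = 0.0112), as did leaving out 5 mM replicate 2 for or30bx1 (1.09, adjusted p = 0.00205). Of the gene lists 0 changed by camera, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.268. Among their members, adjusted over the list alone, 2 passed in lists that did not: the lipase gene lipca in the yolk list at 0.41 ± 0.12 and the eye gene pax6a in the eye and lens list at -0.43 ± 0.13.

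At 6-somites with 0.625 mM, the dim probe set of bmp5 lay higher by 0.71 ± 0.13 and lpcat4, a phospholipid acyltransferase gene, changed by -0.80 ± 0.15 (SE, n = 3, adjusted p = 0.0437 for both). These were the 2 probe sets that changed with limma, and 1067 had an unadjusted p under 0.05. Both calls were lost without the yolk-poor controls, at adjusted p = 0.129 for each, with log2 differences of 0.69 and -0.76, and 1 other probe set passed. Each call was also lost in 5 of 6 fits that left out 1 array, with adjusted p from 0.113 to 0.536 for bmp5 and from 0.1 to 0.342 for lpcat4, while the log2 differences stayed at 0.60 to 0.78 and at -0.72 to -0.86. With 50 added on the linear scale, which damps dim probe sets, bmp5 lay at 0.05 (adjusted p = 0.644) and lpcat4 at -0.14 (adjusted p = 0.000331).

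At 6-somites the lowest dose, 0.00625 mM, gave the largest count. The thyroid hormone receptor gene thrb rose by 1.01 ± 0.20, the autophagy receptor gene nbr1b by 0.90 ± 0.16 and the tyrosine breakdown gene hpda by 0.88 ± 0.18, while rem1, a small GTPase gene, changed by -0.79 ± 0.15, lpcat4 by -0.77 ± 0.15 and arrdc2 by -0.70 ± 0.16 (SE, n = 3, adjusted p from 0.0109 for nbr1b to 0.0407 for arrdc2). With limma 45 probe sets changed, 37 higher by 0.48 to 1.01 and 8 lower by -0.57 to -0.79, and 2134 had an unadjusted p under 0.05. With quantile normalization 27 were higher and 15 lower, and with cyclic loess 27 and 14. The 45 covered 31 named genes, of which 4 were in a fixed list: the keratin gene krt91 at 0.78 ± 0.12, the aldolase gene aldocb at 0.68 ± 0.15, the immediate early gene junbb at 0.66 ± 0.15 and the tailbud gene tbx16 at -0.57 ± 0.13. Those 4 were chosen after their values were seen, and tbx16 rests on a dim probe set, 1 of its 2. A second probe set of arrdc2 pointed the other way, and with 50 added arrdc2 lay at -0.09 (adjusted p = 0.0966). The count was 26, 9 and 117 without control replicate 1, 2 or 3, and 7, 98 and 84 without 0.00625 mM replicate 1, 2 or 3. Single changes leaned on 1 array in part: without control replicate 2, as little as 63.9% of the change of a called probe set was left. The count was 1 with array weights and 0 with only the arrays of the stage, with limma and 1582 at an unadjusted p under 0.05. Compared directly with limma, 1 probe set differed between 0.00625 and 0.625 mM, and 0 between 0.00625 and 5 mM with 1280 at an unadjusted p under 0.05.

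At 21-somites with 5 mM, 6 lists changed with camera and the preset correlation, and with an estimated correlation 1 did, the nervous system list. In the skeletal muscle list 27 of 34 genes lay below control, with a median of -0.18 (camera adjusted p = 7.61e-06). Its leading members were the myosin light chain genes mylz3 at -0.64 ± 0.16 and mylpfa at -0.52 ± 0.16, the troponin gene tnnt3a at -0.80 ± 0.20 and the creatine kinase gene ckmb at -0.59 ± 0.19 (SE, n = 3), and these 4 passed adjusted over the list alone while 0 passed over all genes. With an estimated correlation the list gave adjusted p = 0.136. Without the yolk-poor controls it gave adjusted p = 0.0659 and a median of -0.09, with tnnt3a at -0.40. The lower doses, which share these controls, also lay below them. Mean log2 levels from control to 5 mM were 6.67, 6.07, 6.36 and 6.03 for mylz3, and 7.09, 6.71, 6.93 and 6.57 for mylpfa. Those of ckmb were 6.37, 5.90, 6.11 and 5.78.

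The nervous system list fell, with 32 of 42 genes below control and a median of -0.14 (adjusted p = 8.11e-05). It held with an estimated correlation (adjusted p = 0.00124) and without the yolk-poor controls (adjusted p = 0.000845, median -0.13). The microtubule gene stmn4 at -0.47 ± 0.13 passed adjusted over the list alone, and 0 genes passed over all genes. The next members were fabp7a at -0.45 ± 0.17, the neuronal transcription factor gene neurod1 at -0.36 ± 0.14 and atp1a3a at -0.39 ± 0.15. These 3 also lay below the shared controls at the lower doses. From control to 5 mM the mean log2 levels were 5.74, 5.38, 5.49 and 5.28 for fabp7a. They were 1.91, 1.65, 1.62 and 1.55 for neurod1, and 6.43, 6.11, 6.13 and 6.03 for atp1a3a. At the lower doses, lists were tested only in the mean over stages.

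The p53 and apoptosis list rose, with 20 of 29 genes above control and a median of 0.08 (adjusted p = 0.00382). With an estimated correlation it gave adjusted p = 0.136, and without the yolk-poor controls adjusted p = 0.00507 and a median of 0.05. Over the list alone 3 genes passed and over all genes 0: phlda3, a p53 target and brake on Akt, at 0.59 ± 0.13, rrm2b, a p53 target and ribonucleotide reductase subunit, at 0.56 ± 0.16, and the sestrin gene sesn3 at 0.55 ± 0.18. The fourth member was casp8 at 0.32 ± 0.13. Mean log2 levels of phlda3 at 21-somites were 4.24, 4.35, 4.79 and 4.84 from control to 5 mM. Those of rrm2b were 6.60, 7.25, 7.09 and 7.16. Without the yolk-poor controls the differences at 5 mM were 0.53 for phlda3, 0.27 for rrm2b and 0.28 for sesn3.

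The endoplasmic reticulum stress and amino acid response list had 26 of 33 genes above control and a median of 0.13 (adjusted p = 0.00239). Its leading members were the chaperone genes calr3b at 0.37 ± 0.12, dnajb11 at 0.37 ± 0.14 and hyou1 at 0.35 ± 0.14, and the folate enzyme gene mthfd2 at 0.27 ± 0.13, of which 0 passed by either count. It gave adjusted p = 0.136 with an estimated correlation and 0.0766 without the yolk-poor controls, with a median of 0.09. The oxidative stress response list had 22 of 30 genes above control and a median of 0.11 (adjusted p = 0.0168, and 0 genes by either count). It gave adjusted p = 0.298 with an estimated correlation and 0.524 without the yolk-poor controls, where gpx4a went from 0.67 ± 0.29 to -0.05, blvrb from 0.40 ± 0.20 to 0.01, gclc from 0.26 ± 0.14 to 0.23 and nqo1 from 0.26 ± 0.14 to 0.25. The yolk and lipid transport list had 25 of 32 genes above control and a median of 0.34 (adjusted p = 7.61e-06, and 0 genes by either count). It gave adjusted p = 0.362 with an estimated correlation, and without the yolk-poor controls its median was -0.08 (adjusted p = 0.104). Its leading members were apoeb at 0.30 ± 0.12, serpina1l at 0.90 ± 0.35, tfa at 0.64 ± 0.26 and apobb.1 at 0.44 ± 0.18.

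**Figure D4:**
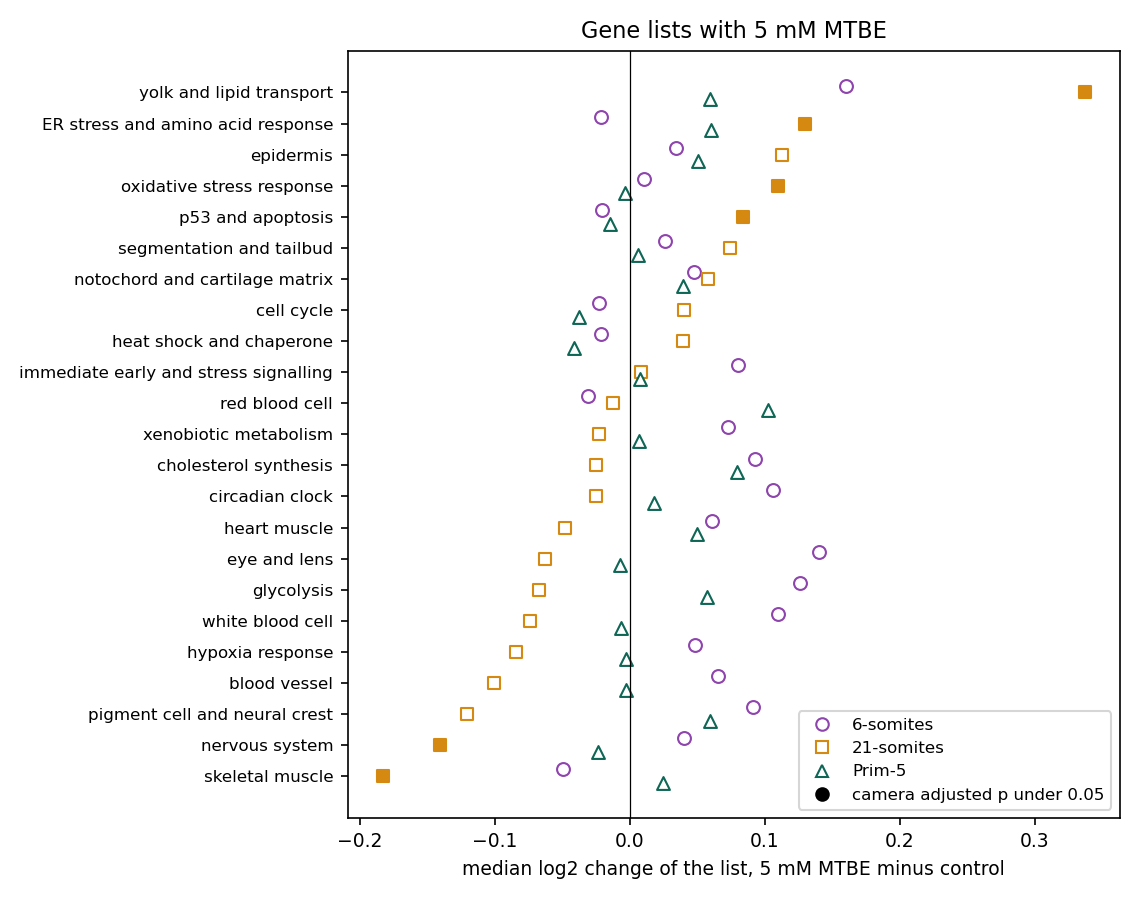
Points are the median log2 difference between 5 mM and control embryos for each of 23 gene lists at 3 stages (n = 3 arrays a group), filled where the camera adjusted p was under 0.05. At 21-somites the filled points run from -0.18 for skeletal muscle to 0.34 for yolk and lipid transport, and the latter lies at -0.08 without the yolk-poor controls.

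No single gene passed with 5 mM at 21-somites. The 3 genes with the smallest p were LOC567909 at 1.51 ± 0.28 (adjusted p = 0.065), krt91 at -0.54 ± 0.12 and phlda3 (adjusted p = 0.373 for both). With limma 0 probe sets changed and 1163 had an unadjusted p under 0.05. Without control replicate 3 at 21-somites, LOC567909 passed at 1.80 (adjusted p = 0.00892). The lists that did not change were eye and lens, pigment cell and neural crest, and epidermis (adjusted p = 0.0644 for each), cell cycle (0.181), glycolysis (0.307), cholesterol synthesis (0.397), segmentation and tailbud and heat shock and chaperone (0.511 for both), white blood cell (0.513), notochord and cartilage matrix (0.618), heart muscle (0.657), xenobiotic metabolism and circadian clock (0.87 for both), red blood cell (0.968), and immediate early and stress signalling (0.976). For the last 4 of these the median, the mean and the test did not all share a sign. In these lists 6 genes passed adjusted over the list alone and 0 over all genes: the heart genes mef2ca at -0.39 ± 0.12 and hand2 at 0.50 ± 0.17, the secretion gene sec23b at 0.42 ± 0.13 and col11a2 at -0.49 ± 0.17 in the notochord and cartilage matrix list, and krt91 at -0.66 ± 0.17 by its brighter probe set and epcam at 0.57 ± 0.18 in the epidermis list. Without the yolk-poor controls hand2 lay at 0.24 and epcam at 0.26.

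At the lower doses no gene passed at 21-somites. With 0.625 mM the pteridine reductase gene qdprb.1 lay at 0.57 ± 0.13, phlda3 at 0.54 ± 0.13 and the Golgi gene cog2 at -0.60 ± 0.15 (SE, n = 3, adjusted p = 0.834 for each), and limma called 0 probe sets with 919 at an unadjusted p under 0.05. With 0.00625 mM the GTPase regulator gene dlc1 lay at 0.59 ± 0.12 (adjusted p = 0.316), rrm2b at 0.65 ± 0.16 and reps1 at -0.62 ± 0.15 (0.854 for both), and limma called 0 with 852. Without control replicate 2 at 21-somites, rrm2b passed at 0.90 (adjusted p = 0.00886).

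At Prim-5 riok1, a kinase gene of small ribosomal subunit assembly, was the gene that changed with 5 mM. It fell by 0.72 ± 0.12 on the log2 scale, -0.72 as a log2 change, from 5.52 ± 0.03 in controls to 4.79 ± 0.10 (SD, n = 3, limma adjusted p = 0.0177). It was the only probe set of 15502 past the threshold, and 578 had an unadjusted p under 0.05, fewer than the 775.1 due by chance. The call was lost when any control array or 5 mM replicate 2 or 3 was left out, with adjusted p from 0.0707 to 0.241 and log2 changes from -0.67 to -0.76. It was also lost with 50 added (-0.30, adjusted p = 0.189) and with a replicate block (adjusted p = 0.0589). Of the lists 0 changed by camera, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.233. The lysozyme gene lyz in the white blood cell list passed adjusted over that list alone, at 0.64 ± 0.19, and was named after its value was seen. Its arrays with 5 mM varied widely, with an SD of 0.588 against 0.174 in controls.

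At Prim-5 with 0.625 mM the homeobox gene lhx2a lay at -0.51 ± 0.13, the cytochrome gene cyp2aa6 at -0.66 ± 0.18 and poglut2 at -0.40 ± 0.11, and with 0.00625 mM med10 at 0.48 ± 0.13, afg2b at -0.40 ± 0.12 and tnr at -0.42 ± 0.13 (SE, n = 3, adjusted p = 1 for each). None of the 6 passed. With limma 0 probe sets changed at either dose, and 535 and 313 had an unadjusted p under 0.05.

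Averaged over the 3 stages, 4 lists passed with 5 mM by camera and the preset correlation, and no single gene passed. The nervous system list had 29 of 42 genes below control and a median of -0.05 (adjusted p = 0.00273). Its medians by stage were 0.04 at 6-somites, with 24 of 42 genes above control, -0.14 at 21-somites and -0.02 at Prim-5, and it passed at 21-somites alone. It held with an estimated correlation (adjusted p = 0.011) and without the yolk-poor controls (adjusted p = 0.0389). Without replicate 2 the call was lost, with a median of -0.05 and adjusted p = 0.183. Its leading members were stmn4 at -0.20 ± 0.07, neurod1 at -0.21 ± 0.08, and the synaptic genes snap25b at -0.18 ± 0.08 and syt1a at -0.19 ± 0.08 (SE, n = 9 arrays a group). The skeletal muscle list had 26 of 34 genes below control (median -0.07, adjusted p = 0.00273), with adjusted p = 0.471 with an estimated correlation and 0.418 without the yolk-poor controls (median -0.04). Its member with the smallest p, myf6, pointed the other way at 0.23 ± 0.09, beside srl at -0.14 ± 0.08, actc1b at -0.12 ± 0.07 and mylpfa at -0.16 ± 0.09. The endoplasmic reticulum stress and amino acid response list had 28 of 33 genes above control (median 0.05, adjusted p = 0.0108), with adjusted p = 0.447 with an estimated correlation and 0.418 without the yolk-poor controls (median 0.05). Its member slc3a2b, an amino acid transporter gene, lay at 0.32 ± 0.09 and passed adjusted over the list alone, and phgdh lay at 0.19 ± 0.07, vldlr at -0.20 ± 0.08 and xbp1 at 0.25 ± 0.11.

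The yolk and lipid transport list rose in this mean with 30 of 32 genes above control (median 0.19, adjusted p = 1.64e-06), with adjusted p = 0.582 with an estimated correlation, and without the yolk-poor controls its median was -0.02 (adjusted p = 0.217). Its leading members were apoeb at 0.19 ± 0.07, tfa at 0.37 ± 0.15, ctsla at 0.22 ± 0.10 and serpina1l at 0.39 ± 0.20. Another 4 genes passed adjusted over lists that did not change: fkbp5 at -0.26 ± 0.07, epcam at 0.37 ± 0.10, rrm2b at 0.30 ± 0.09 and pax6a at -0.25 ± 0.07. The 3 genes with the smallest p were riok1 at -0.32 ± 0.07, pdlim7 at -0.35 ± 0.08 and the folate enzyme gene fpgs at 0.35 ± 0.08, with adjusted p = 0.721 for each. With limma 0 probe sets changed and 847 had an unadjusted p under 0.05. In this mean vegfaa lay at -0.01 ± 0.07 (adjusted p = 0.999) and vegfc at 0.00 ± 0.11, the blood vessel list at a median of -0.00 (adjusted p = 0.602) and the hypoxia response list at -0.01 (0.602). Members with the smallest p were crip2 at -0.14 ± 0.08, plvapb at 0.16 ± 0.09, erg at -0.14 ± 0.09 and ephb4a at 0.10 in the former and p4ha2 at -0.08, higd1a at -0.08, mxi1 at 0.15 ± 0.08 and bnip3lb at 0.19 ± 0.12, which lay at -0.03 without the yolk-poor controls.

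Averaged over the stages with 0.625 mM, 6 lists changed with camera: yolk and lipid transport (median 0.19, adjusted p = 9.55e-07), epidermis (0.04, 0.0277), endoplasmic reticulum stress and amino acid response (0.06, 0.0277), glycolysis (0.08, 0.0354), nervous system (-0.04, 0.0354) and oxidative stress response (0.06, 0.0404). With an estimated correlation 0 of the 6 passed, with adjusted p from 0.156 for nervous system to 0.381 for yolk and lipid transport and oxidative stress response, and 0 passed without the yolk-poor controls, with adjusted p from 0.347 to 0.85. Members with the smallest p were the yolk genes fabp1b.1 at 0.45 ± 0.17, serpina1l at 0.45, apoeb at 0.14 and foxa3 at 0.18, and the epidermis genes epcam at 0.26 ± 0.10, krt17 at 0.21, evplb at 0.16 and krt5 at 0.17. In the stress lists they were pdia6 at 0.20 ± 0.08, slc3a2b at 0.21, mthfd2 at 0.16, calr3a at 0.14, txnipb at 0.27 ± 0.09, gpx4a at 0.38, tktb at 0.24 and park7 at -0.15. Without replicate 1 at each stage, serpina1l lay at -0.0188, gpx4a at -0.0171 and tktb at -0.0386, and the other named members kept their direction. In glycolysis they were gapdhs at 0.34 ± 0.09, which passed adjusted over the list alone, tpi1b at 0.39, gapdh at 0.40 and gpia at 0.14, and in the nervous system list th at 0.15 ± 0.08, gfap at -0.11, atp1a3a at -0.16 and syt1a at -0.15. In the heat shock list, which did not change, fkbp5 at -0.23 ± 0.07 passed adjusted over the list alone. With limma 0 probe sets changed and 707 had an unadjusted p under 0.05, with fam210ab at -0.31 ± 0.07, nr1h3 at 0.42 ± 0.10 and zgc:86738 at 0.35 ± 0.09 nearest (adjusted p = 0.993 for each).

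With 0.00625 mM, 2 lists changed in the mean over stages: yolk and lipid transport (median 0.25, adjusted p = 3.76e-09) and glycolysis (0.09, 0.0132). Both gave adjusted p = 0.388 with an estimated correlation, and adjusted p = 0.874 and 0.246 without the yolk-poor controls. Their leading members were the lysosomal protease gene ctsba at 0.83 ± 0.35, tfa at 0.36 ± 0.15, foxa3 at 0.20 and serpina1l at 0.46, and aldocb at 0.28 ± 0.09, tpi1b at 0.38 ± 0.13, ldha at 0.23 and gapdhs at 0.21, and 0 members passed by either count. In lists that did not change, rrm2b at 0.34 ± 0.09 passed adjusted over the list alone. With limma 0 probe sets changed and 916 had an unadjusted p under 0.05, with krt91 at 0.34 ± 0.07 (adjusted p = 0.25), lpcat4 at -0.40 ± 0.09 (0.301) and kiz at -0.35 ± 0.08 (0.729) nearest.

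Over the 4 doses in order, 1 gene changed at each stage. At 6-somites bmp5, read by a dim probe set, had mean log2 levels of 1.45 ± 0.24 in controls and 1.91, 2.16 and 2.15 ± 0.12 with 0.00625, 0.625 and 5 mM (SD, n = 3), a slope of 0.23 ± 0.04 a step (SE, limma adjusted p = 0.0432). At 21-somites LOC567909, a gene without a descriptive name, had 3.28 ± 0.53, 3.54, 4.15 ± 0.84 and 4.79 ± 0.19, a slope of 0.51 ± 0.09 (adjusted p = 0.018). At Prim-5 riok1 had 5.52, 5.30, 5.18 and 4.79, a slope of -0.23 ± 0.04 (adjusted p = 0.0176). With limma 1060, 1023 and 566 probe sets had an unadjusted p under 0.05. Leaving out any replicate number ended the call of bmp5 (adjusted p from 0.115 to 0.244) and of riok1 (0.267 to 0.451), while the slopes stayed at 0.207 to 0.255 and at -0.211 to -0.239. The call of LOC567909 ended without replicate 2 (slope 0.489, adjusted p = 0.388) and without the yolk-poor controls (0.446, adjusted p = 0.513). That of bmp5 also ended without the yolk-poor controls (slope 0.228, adjusted p = 0.097). With 50 added all 3 calls ended, with slopes of 0.0155 for bmp5 (adjusted p = 0.615), 0.126 for LOC567909 (adjusted p = 0.0936) and -0.0954 for riok1 (adjusted p = 0.138).

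**Figure D5:**
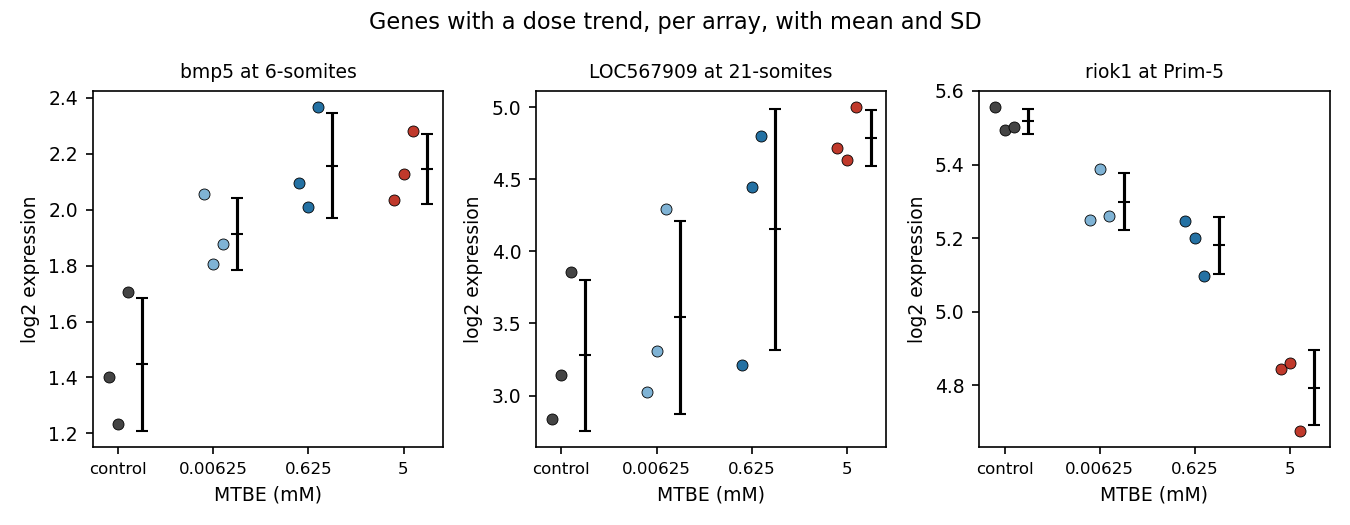
Points are log2 values of single arrays (n = 3 for each dose) for bmp5 at 6-somites, LOC567909 at 21-somites and riok1 at Prim-5, and the bars beside them are the mean and SD. The mean of riok1 goes from 5.52 in controls to 4.79 with 5 mM.

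The order of the doses was also read without shared controls, in probe sets picked at 5 mM. At Prim-5 the 1 changed probe set, of riok1, moved the same way from 0.00625 to 0.625 mM. Of the 100 probe sets with the smallest p at 5 mM, a set chosen after the counts were seen, 27% did so at 6-somites, 41% at 21-somites and 59% at Prim-5. In other splits of those arrays the percent moving the same way or the other way, whichever was larger, reached 74, 69 and 57. Of the 10 splits, the real one included, 2, 6 and 1 lay at least as far from 50% as the real percent. With 10 splits no share can lie under 0.05.

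Whether treated embryos lagged behind or ran ahead of controls was asked with the stage score. At 21-somites the score was 0.78 ± 0.08 with 5 mM and 0.95 ± 0.06 in controls (SD, n = 3), a difference of -0.17. That is -3.78% of the distance between Prim-5 and 6-somites controls. The lower doses also lay below controls, at 0.83 ± 0.09 with 0.00625 mM and 0.86 ± 0.05 with 0.625 mM. All 3 arrays with 5 mM lay below all 3 controls, and the exact permutation p of 0.1 is the smallest that 3 against 3 can give. At 6-somites the difference was 0.06 (exact permutation p = 0.6), at Prim-5 0.02 (exact permutation p = 0.8), and over the 3 stages -0.03 (exact permutation p = 0.428).

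Whether 5 mM acted differently between stages was tested for each probe set and found for none. The limma F test called 0 probe sets, with 1188 at an unadjusted p under 0.05, and phlda3, the chromatin remodeller gene smarca5 and mylz3 had the smallest p (adjusted p = 0.366 for each).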

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

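The tests of lists between stages, of array quality, of the lists without the yolk-poor control at 21-somites and of 1 deviating array were chosen after the results were seen.

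The 6 lists that changed with 5 mM at 21-somites were tested for a difference of that effect between stages, in 18 tests, and 8 differences passed with camera and the preset correlation. All 8 involve 21-somites, which the choice of these lists by their change at 21-somites favoured. Between 21-somites and 6-somites the median difference of the effect was -0.121 for skeletal muscle (adjusted p = 0.0478), -0.152 for the nervous system (0.0268), 0.128 for p53 and apoptosis (0.0172) and 0.11 for endoplasmic reticulum stress and amino acid response (0.0189). Between 21-somites and Prim-5 it was -0.205 for skeletal muscle (1.93e-05), -0.099 for the nervous system, 0.323 for yolk and lipid transport and 0.106 for p53 and apoptosis (0.0157 for these 3). With an estimated correlation 0 of the 8 passed, with adjusted p from 0.062 to 0.527. Without the yolk-poor controls the adjusted p of skeletal muscle between 21-somites and 6-somites was 0.623, and the other 7 lay between 0.0252 and 0.0367. Of those 7, yolk and lipid transport pointed the other way without these controls, with a median difference of -0.0985 (adjusted p = 0.0308). Between Prim-5 and 6-somites, yolk and lipid transport (0.154, adjusted p = 0.0252) and endoplasmic reticulum stress and amino acid response (0.075, adjusted p = 0.0302) passed without these controls and not with them. The samples came in 12 groups of 3, too few to test single samples for standing apart.

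Control replicate 1 at 6-somites and at 21-somites stood apart from the other controls of their stage. A wrong stage label was argued against. Their stage score differed from the other controls by at most -9.13% of the distance between controls of the 2 other stages. Lower quality of the whole array stays open: the residual SD over all probe sets was 1.39 and 1.64 times the median of all arrays, around the bound of 1.5, and the at most 1.29 outside the probe sets of largest deviation decides nothing, since those were picked in these arrays. A lower content of yolk-associated RNA in these pools may account for it: the yolk and lipid transport list lay at -0.677 and -1.55, and other lists between -0.257 and 0.225. It cannot be told apart from other causes, since the test asked for a shift beyond 1 log2 unit in both arrays and the array at 6-somites fell short of it, and no biological explanation was tested.

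The 6 lists that changed with 5 mM at 21-somites may in part reflect the yolk-poor control, since 2 of the 6 were called without it. For the nervous system list that was argued against as the whole cause, since it was still called without that array (camera adjusted p = 8e-04). Of its shift 93.6% was left (interval 50.3 to 136), a bound only just cleared. For p53 and apoptosis 58.5% was left (interval -20.3 to 334), so it cannot be told apart. Both intervals come from resampling the genes of the list with the arrays held fixed. They treat related genes as independent and do not measure the spread between arrays. Slower development with 5 mM stays open. The stage score differed by -0.144 from the mean of the other 2 controls (exact permutation p = 0.2), and 3 of 3 arrays with 5 mM lay below both. The scores with 0.00625 and 0.625 mM, 0.83 and 0.86, also lay below the 0.95 of controls. An effect of MTBE on these genes stays open as well. A control group apart from all MTBE groups was not tested for these lists. With 10 splits of the 6 arrays, too few for a share under 0.05, the real count was 6 lists. The other splits, which mix 5 mM and control arrays, each called 2 to 4 lists, with a median of 3.

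For the 45 probe sets changed at 6-somites with 0.00625 mM, 1 deviating array as the whole cause was argued against, since a median of at least 90.5% of their change was left without any 1 of the 6 arrays. Calls were lost all the same: 5 of them were kept without 0.00625 mM replicate 1, 7 without control replicate 2, 18 without control replicate 1 and 31 to 33 without each of the others. Leaving out 1 array at a time cannot detect arrays that deviate in opposite directions, and that was not tested. Control replicate 2 and 0.00625 mM replicate 1 lay at the 2 ends of the fourth principal component, at 17.2 and -17.3. Dim probe sets cannot be told apart from a response, since 64.4% lay below the median level. Nor can a control group apart from all MTBE groups, since the other doses showed a median of 49.6% of the change where simulated groups with no effect gave 50 (37.4 to 58.1). An effect of the lowest dose stays open, and the highest of the other splits, too few at 10 for a share under 0.05, gave 22.

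In the other comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real count and the highest other were 0 and 4 with 5 mM and 2 and 1 with 0.625 mM at 6-somites, and 0 and 0, 0 and 1, and 0 and 0 at 21-somites from the highest to the lowest dose. At Prim-5 they were 1 and 0, 0 and 0, and 0 and 1 in the same order. For control stages they were 3505 and 407, and 1091 and 2, and for lists with 5 mM 0 and 4 at 6-somites and 0 and 2 at Prim-5.

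Of 100 splits, 100 gave as many probe sets as the real 0 for each mean over stages (highest other 5, 2 and 1) and for the F test (27), and with a real count of 0 the splits decide nothing. Chance was not excluded for the trends, where 31, 5 and 11 splits gave at least the real 1 (highest other 92, 3 and 3). The 92 and the 27 are far above the real counts and may come from a structure of the samples, which was not tested in these splits. For lists in the means, chance was not excluded with 5 mM (4, highest other 5, 10 splits) or 0.00625 mM (2, highest other 5, 38 splits). With 0.625 mM 3 of 100 splits gave the real 6 or more (highest other 8), a share with an interval from 0.623% to 8.52%, so it is under 0.05 only as drawn.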

How the results depend on the processing

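Array weights, the fits without the yolk-poor controls and the order of the 100 probe sets with the smallest p were chosen after seeing the data, and the cause of a difference was not tested except where a smaller set of probe sets or arrays was used. The named results pool control stages and MTBE doses. Of 187 gene results that passed, 142 kept their direction and side of the threshold in every alternative run for them and 0 turned. Of 157 not passing 132 did and 15 turned. Every named gene call with MTBE was lost in some alternative, so the 142 lie between control stages. Of 35 list calls 12 kept both and 5 turned, and of 149 list results without a call 75 turned direction. After that was seen, values are given for called lists, blood vessel and hypoxia response. Among list calls with MTBE, only that of the nervous system at 21-somites was kept in every alternative. Probe sets changed at 6-somites with 5 mM numbered 1 with quantile normalization, 2 with 50 added, 2 with a replicate block and 1 without the yolk-poor controls. With 0.625 mM they numbered 1 with 50 added and without the yolk-poor controls, and 0 at or above the median level, with only the arrays of the stage, with trend and robust settings and with array weights. With 0.00625 mM they numbered 77 with 50 added (33 shared with the 45), 8 at or above the median level, 0 with only the arrays of the stage and 1 with array weights. With a replicate block they numbered 1 at 21-somites with 5 mM, 0 at Prim-5 with 5 mM and 0 for the Prim-5 trend, but replicate numbers did not pair arrays: the median residual correlation of the same number was 0.00017, -0.017 and -0.012 by stage. With 50 added 0 changed at Prim-5 with 5 mM, and the trends gave 2, 0 and 2, with 0 of these shared with the calls of bmp5, LOC567909 and riok1. The 6-somites trend gave 0 at or above the median level, with only the arrays of the stage, with trend and robust settings and with array weights. The 21-somites trend gave 2 with cyclic loess, at or above the median level and with array weights, and 0 with only the arrays of the stage, with trend and robust settings and without the yolk-poor controls. The mean with 0.00625 mM gave 1 without the yolk-poor controls. Lists numbered 1 at 21-somites and 1, 0 and 0 in the means from the highest dose with an estimated correlation, and 2, 1, 0 and 0 without the yolk-poor controls. At or above the median level they numbered 7 and 5 in the means with 5 and 0.00625 mM, and with quantile normalization 1 in the mean with 0.625 mM. The dose order at Prim-5 was 59% with 100 probe sets, and had no value with all arrays at 6-somites and 21-somites. Leaving out replicates gave 0 to 2, 0 to 4 and 7 to 117 probe sets at 6-somites, 0 to 1, 0 to 0 and 0 to 1 at 21-somites and 0 to 2, 0 to 0 and 0 to 0 at Prim-5 from the highest dose, 0 to 0 for the means and the F test, 1 to 2, 0 to 1 and 0 to 4 for the trends, and 2908 to 3315 and 753 to 1007 for control stages. Lists ranged over 0 to 1, 2 to 8 and 0 to 0 by stage with 5 mM and 1 to 6, 0 to 6 and 0 to 3 in the means. Stage score differences ranged from 0.00329 to 0.096, from -0.218 to -0.144, from -0.0184 to 0.042 and from -0.0498 to -0.0108 in the mean. The dose order at Prim-5 rested on 1 probe set, so leaving out replicates says nothing about it. Directions turned for genes that had not passed. With replicates left out, vegfaa ranged from -0.0844 to 0.0801 at Prim-5 and from -0.0703 to 0.0419 in the mean, where it was 5.29e-05 with 50 added. In the same way vegfc ranged from -0.0694 to 0.226, from -0.141 to 0.132 and from -0.227 to 0.0647 by stage and from -0.2 to 0.203 in the mean. It was 0.00185 with cyclic loess, 0.0146 without the yolk-poor controls and 0.0507 with array weights at 21-somites, 0.0537 with array weights at Prim-5, and -0.0104 with quantile normalization, -0.00386 with cyclic loess and -0.000552 with 50 added in the mean. Without the yolk-poor controls bnip3lb was -0.0398 at 21-somites and -0.0285 in the mean, gpx4a -0.052 at 21-somites, higd1a 0.00867 and serpina1l -0.0307 in the mean with 5 mM. With replicates left out, bnip3lb ranged from -0.0398 to 0.659 and gpx4a from -0.052 to 1.05 at 21-somites, higd1a from -0.212 to 0.0378 and xbp1 from -0.00126 to 0.375 in the mean with 5 mM, and serpina1l from -0.0188 to 0.679, gpx4a from -0.0171 to 0.577 and tktb from -0.0386 to 0.41 in the mean with 0.625 mM. The tests of lists turned, at these medians: hypoxia response 0.0418 at 6-somites and -0.00299 at Prim-5 with the mean of the probe sets of a gene, and with replicates left out 0.00784 to 0.0818 at 6-somites, -0.0691 to 0.0161 at Prim-5 and -0.00611 to 0.0117 in the mean. Blood vessel ranged from -0.0314 to 0.0831, from -0.019 to 0.0128 and, in the mean, from -0.0331 to 0.0206 in the same way, and was 0.00617 at Prim-5 at or above the median level and 0.0205 in the mean without the yolk-poor controls. Yolk and lipid transport gave -0.0816 at 21-somites, and -0.0224, -0.0266 and 0.0105 in the means from the highest dose, without the yolk-poor controls. With replicates left out it ranged from -0.0816 to 0.635 at 21-somites, from 0.03 to 0.293 in the mean with 5 mM and from -0.0561 to 0.322 with 0.625 mM, where oxidative stress response ranged from -0.00893 to 0.112. The direction is that of the test, so a median can keep its sign. Without scanner files the signal over background that limits dim probe sets is unknown.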

Other observations

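The genes given here were chosen after their values were seen.

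Control embryos also showed changed genes in lists that did not change as a whole. From 6-somites to 21-somites the neural crest gene crestin rose by a log2 change of 1.49 ± 0.15 (SE, n = 3) and the early eye field gene rx3 changed by -2.1 ± 0.17. The chaperone genes hsp90aa1.1, which is also in the skeletal muscle list, and hspb1 changed by 1.90 ± 0.11 and -1.82 ± 0.14, the stress signalling genes ccn2a and dusp2 by 2.56 ± 0.16 and -2.16 ± 0.17, the epidermis genes icn and lye by 2.1 ± 0.24 and -1.73 ± 0.12, and the clock gene bmal1b by 0.77 ± 0.11. Each had a limma adjusted p of 2.1e-06 or less.

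From 21-somites to Prim-5 the pigment genes gch2, dct and mitfa rose by 2.21 ± 0.15, 1.57 ± 0.14 and 0.73 ± 0.17. The lens crystallin genes crybb1 and cryba4 rose by 1.27 ± 0.15 and 0.91 ± 0.14, the lysozyme gene lyz by 1.87 ± 0.19, the clock gene per2 by 1.1 ± 0.21 and the protein folding gene pdia4 by 1.2 ± 0.18. The largest limma adjusted p among these 8 was 0.00412, for mitfa.

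A control probe set of the array for green fluorescent protein had a mean log2 level of 2.71, between the 2 red fluorescent protein probe sets at 2.98 and 2.18. A signal of the transgene was therefore not shown to lie above background.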
